A study of Homo sapiens with 15 samples.

How the data were processed

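Gene expression was measured in 15 samples of HMLE cells, an immortalized human mammary epithelial cell line grown in mammary epithelial medium. There were 5 groups of 3 arrays: parental cells, cells carrying the empty vector, and cells transduced with vectors for Twist, Snail or Slug. Total RNA was made into biotin-labelled cRNA and hybridized to Illumina bead arrays.

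The deposited non-normalized table gives the intensity of 24526 probes on each array, on a linear scale and without detection p-values. The processed values deposited by the authors are intensity values too. Each of their columns matched the non-normalized column multiplied by a single factor, from 0.7396 to 1.3407, which gave every array a mean of 682.2. The largest residual was 0.94 of the tolerance allowed for rounding and for the precision of the factor. The authors did not state this scaling in words. Neither the scanner software nor any background step before the table was stated. The mean intensity per array ran from 508.9 to 922.4 and the median from 108 to 148.1. No depth can be computed for arrays, and the number of arrays per group limits the precision.

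The non-normalized intensities were corrected with the normexp method at an offset of 50, quantile normalized between arrays and put on the log2 scale with limma 3.58.1 in R 4.3.3. Probes were kept when they lay above the 40th percentile of their own array on at least 3 arrays, a rule that uses no group labels. This kept 16248 probes, of which 14667 had a gene symbol. Probes with several symbols did not occur, and the 2692 probes of the table without a symbol stayed out of the gene counts. Where several probes named a gene, the probe with the highest mean over all 15 arrays stood for it, which left 12079 genes.

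Group means were fitted with limma to all 15 arrays at once, with 10 residual and 10.2 prior degrees of freedom. No replicate block was used, because the letters a, b and c of the samples are not described as shared cultures or days. There were 8 comparisons: each factor against parental, vector against parental, each pair of factors, and the mean of the 3 factors against parental. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested together with an absolute log2 fold change of at least 1. Fold changes are given with the standard error of the fit. Tests were two-sided.

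The share of protein kinases among called genes was compared with that among other genes by Fisher's exact test. For 31 gene lists, camera was run with a preset correlation of 0.01 between genes, and Benjamini-Hochberg adjustment covered all 248 list tests. Of these, 93 passed with the preset correlation, and 65 of the 93 also passed with a correlation estimated for each list. Each list's members were also counted with the p-values adjusted over the list alone. This second count kept the fold limit. Since every gene past that limit had an adjusted p of at most 0.00023, it was bound to repeat the first count. The lists covered kinases, epithelial and mesenchymal genes, matrix, ligands and signalling pathways, metabolism, stress and growth, and markers of other cell types.

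The comparisons, the lists, the alternatives and the rule for naming genes were set before the data were examined. The rule named the introduced factors and a fixed set of genes, among them PRKCA, FOSL1, EGFR, CDH1, CDH2, VIM and FN1. It added the 8 largest rises and falls of each factor and of their mean, and the 5 largest of the other comparisons, among called genes whose 2 groups did not overlap. It also took up to 4 called members of each list and the kinases changed the same way by all 3 factors.

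The method was tested on simulated data with known changes between groups of 3 arrays. All simulated changes of 1.5 and 2 on the log2 scale were recovered. Changes of 0.75 were recovered by the adjusted p alone (100%) but not with the fold limit (0%). Unchanged genes called numbered 0 with the fold limit and 11 with the adjusted p alone.

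The alternatives were no background correction, an offset of 16, median scaling, cyclic loess, the deposited scaled values, no filter and a filter at the array median. Further ones were other call limits, the mean of all probes of a gene, a fit of the compared groups only, array weights, an intensity-dependent and robust prior, a replicate block, other control groups, an estimated correlation in the list tests, and leaving out each array. Array brightness as a covariate, and leaving out each array for single genes, were added after seeing the data. ERBB3, MKNK2, MST1R, SYK, LYN, NOTCH3 and SPRR2D fell outside the rule for naming genes and were chosen after their values were seen. Gene symbols were checked against a current human annotation, which also gave the order of genes along the chromosomes for 1 test of neighbouring genes. Positions of single genes are not given. Splits of the samples and simulations of unchanged groups used 100 draws where more existed. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.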

Results

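Expression was measured on Illumina bead arrays in HMLE cells, immortalized human mammary epithelial cells. The 15 arrays form 5 groups of 3: parental cells, empty-vector cells, and cells transduced to express Twist, Snail or Slug, transcription factors known to drive epithelial cells into a mesenchymal state. The series compared cells expressing each factor with parental cells and looked for kinases that differ between the epithelial and the mesenchymal state. Mean intensity per array was 508.9 to 922.4, and 12079 genes were tested. Below, changes are log2 fold changes with the standard error of the fit after ±, levels are normalized log2 intensities with the SD, every group has n = 3 arrays, and adjusted p-values are from limma. These p-values measure only the spread between arrays, which may be technical, since nothing says that the 3 arrays of a group come from separate cultures.

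The groups separated on the leading axis of variation. Principal component 1 held 45.7% of the variance, with a mean score of -14.7 in parental, -22 in vector, 4.85 in Twist, 12 in Slug and 19.8 in Snail arrays. Component 2 held 16.3% and set Twist (13.8) apart from Slug (-13.5).

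**Figure D1:**
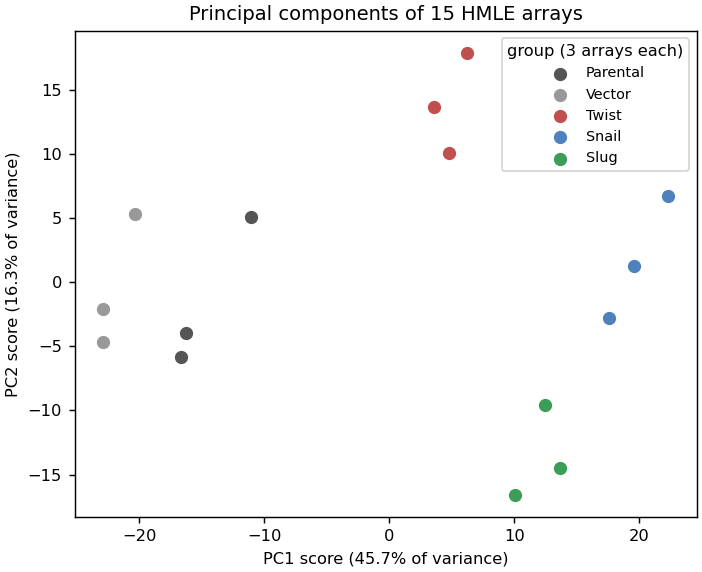
Scores of the 15 arrays on principal components 1 and 2 of the normalized log2 intensities, 1 point per array, coloured by group. Component 1 holds 45.7% of the variance, and the parental and vector arrays lie on its negative side and all factor arrays on its positive side.

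The introduced factors themselves were not seen to rise in their own groups. The probe for SNAI1, the gene of Snail, stayed dim everywhere, at 5.83 ± 0.1 in Snail and 5.89 ± 0.06 in parental arrays, and did not pass the filter. In a fit without the filter its difference was -0.06 ± 0.08 (adjusted p = 0.73). TWIST1 was 0.18 ± 0.1 above parental in the Twist arrays (adjusted p = 0.24) and 0.56 ± 0.1 above it in the Snail arrays (adjusted p = 0.00011). SNAI2, the gene of Slug, was 10.01 ± 0.19 in the arrays labelled Slug and 10.57 ± 0.27 in parental arrays. This difference of -0.57 ± 0.13 (adjusted p = 0.0039) would go against the label only if the probe saw the introduced transcript. In the Twist arrays SNAI2 was 0.94 ± 0.13 above parental (adjusted p = 2.9e-05), and it passed the fold limit without parental replicate a (1.09) or without Twist replicate b (1.03). Whether these probes lie inside the introduced sequences is not known, so they neither bear out nor refute the labels. The names Twist, Snail and Slug below mean the arrays labelled so.

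Empty-vector cells differed from parental cells in a small set of genes past the fold limit. By adjusted p alone 1764 genes differed, against 1793 between Twist and parental. FGFR3, a receptor tyrosine kinase, rose by 1.52 ± 0.09 (adjusted p = 2.3e-09), and KREMEN2, a receptor of the Dickkopf proteins that inhibit Wnt signalling, by 1.33 ± 0.09. FST, the activin antagonist follistatin, fell most, from 13.11 ± 0.05 to 11.03 ± 0.2 (-2.08 ± 0.09, adjusted p = 4.8e-12). CXCL8 (-1.66) and IL1B (-1.17), both inflammatory cytokines, fell too, as did the tight-junction gene CLDN1 (-1.38) and the gelatinase MMP9 (-1.21). In all, 33 genes were called, 18 higher and 15 lower. This count was 21 without background correction, 20 with the deposited values and 60 with an offset of 16, and with median scaling 10 genes were higher and 20 lower. FGFR3 rests on its brighter probe, because another probe changed by 0, and the mean of its probes changed by 0.76 and was not called. KREMEN2 was at 0.83 with the mean of its probes and was not called either.

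Among gene lists, interferon response genes were higher in vector arrays (median 0.16, camera adjusted p = 0.0013), although no single member of the 27 was called, and 7 were higher by adjusted p alone. Cholesterol synthesis genes were lower (median -0.18, adjusted p = 0.0053), with 6 of 17 lower by adjusted p alone. The 23 cytokines and chemokines were lower (median -0.08, adjusted p = 0.012), with 2 called, and this call was lost with an estimated correlation (adjusted p = 0.065 with an estimated correlation). Lower medians were also found for the epithelial transcription and splicing regulators (-0.16, adjusted p = 0.021, then adjusted p = 0.056 with an estimated correlation) and the epidermal differentiation genes (-0.13, adjusted p = 0.028, then adjusted p = 0.19 with an estimated correlation).

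Twist arrays gained matrix and mesenchymal transcripts. LOX, the lysyl oxidase that cross-links collagen, rose from 7.23 ± 0.04 to 9.77 ± 0.07 (2.54 ± 0.09, adjusted p = 6.8e-14). Further large rises were COL8A1 (2.28 ± 0.09), COL1A1 (2.08 ± 0.09) and SPOCK1 (2.07 ± 0.08), which encode 2 collagen chains and a matrix proteoglycan. The mesenchymal genes CDH2 (N-cadherin, 1.42 ± 0.13), VIM (vimentin, 1.22 ± 0.09), FN1 (fibronectin, 1.22 ± 0.08) and PRRX1 (1.83 ± 0.11) rose as well. HAS3, a hyaluronan synthase, fell most (-2.2 ± 0.08, adjusted p = 6.8e-14), followed by LTB (-1.99 ± 0.14), FGFR3 (-1.87 ± 0.09) and MMP9 (-1.84 ± 0.1). CDH1, the gene of E-cadherin, was 10.87 ± 0.1 against 11.53 ± 0.19 in parental arrays, a difference of -0.65 ± 0.1 (adjusted p = 7.5e-05) that did not reach the fold limit.

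In all, 115 genes were called between Twist and parental, 66 higher and 49 lower. Of the 35 mesenchymal markers, 11 rose, and 11 did so adjusted over the list alone (camera adjusted p = 1.5e-25). Here and below, counts adjusted over the list alone keep the fold limit, which decides the calls, so they add no evidence. Fibroblast markers, which share members with the mesenchymal and collagen lists, moved with them: 3 of 13 rose, 3 adjusted over the list alone (adjusted p = 7.9e-09). Of 21 collagens, 3 rose and COL18A1 fell, 3 and 1 adjusted over the list alone (adjusted p = 1.4e-06). Of 25 matrix proteases, lysyl oxidases and inhibitors, LOX and PLAT rose and MMP9 fell (adjusted p = 0.00044). Of 26 epithelial junction genes 2 fell, CLDN1 (-1.46) and CLDN7 (-1.37), 2 adjusted over the list alone (median -0.24, adjusted p = 2.1e-09). The list of other epithelial surface and protease genes was lower too (median -0.32, adjusted p = 1.5e-06), with PRSS8 called. KLF4 rose by 1.48 while the list of epithelial transcription and splicing regulators it belongs to was lower (median -0.25, adjusted p = 0.009). Epidermal differentiation genes were lower (median -0.33, adjusted p = 0.00016), with PI3 and KLK7 falling and LCN2 rising. Of 32 glycolysis and hypoxia genes 5 fell, 5 adjusted over the list alone, among them DDIT4 (-1.57) and ADM (-1.29) (median -0.34, adjusted p = 3.5e-09). Interferon response genes were higher (median 0.2, adjusted p = 0.00013), with IFI6 called.

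With the vector arrays as control, 82 of the 115 Twist calls were kept (71.3%). Calls that ended include CLDN1 (-0.08), CLDN7 (-0.78), MMP9 (-0.62), IL1B (-0.44), SERPINB1 (-0.79), ALDH1A3 (-0.43), IFI6 (0.61), PLAT (0.86) and KLK7 (-0.6). The list calls for interferon response (camera adjusted p = 0.47), epidermal differentiation (0.32) and epithelial regulators (0.61) ended too. HAS3, at -0.94 in vector against parental, was at -1.26 in Twist against vector, where LTB was at -2.21 and FGFR3 at -3.39. SNAI2 passed the fold limit against vector (1.15). With the mean of all probes, REPS2 (2.14 with its brightest probe) was at 0.94 and KLK7 at -0.7, both under the fold limit. LCN2 was at 0.95 without background correction.

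Snail arrays showed the most called genes of the 3 factors, with strong losses of epithelial genes. COL1A1 rose most, from 7.31 ± 0.03 to 10.54 ± 0.1 (3.24 ± 0.09, adjusted p = 9.3e-16), followed by HMOX1, the heme oxygenase of the oxidative stress response (2.84 ± 0.15), SPOCK1 (2.76 ± 0.08) and the actin-binding TAGLN (2.61 ± 0.09). RAB25, a GTPase of epithelial membrane recycling, fell from 10.69 ± 0.05 to 8.04 ± 0.07 (-2.65 ± 0.08, adjusted p = 3.7e-15). MAL2 (-2.56 ± 0.1), MAPK13 (-2.53 ± 0.11), CLDN1 (-2.49 ± 0.11) and KRT15 (-2.34 ± 0.11) fell as strongly. CDH1 fell by 1.45 ± 0.1, and CDH2 (1.94 ± 0.13), VIM (1.56 ± 0.09) and FN1 (1.55 ± 0.08) rose.

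In all, 298 genes were called between Snail and parental, 110 higher and 188 lower. Of 26 epithelial junction genes 12 fell, 12 adjusted over the list alone, with CLDN1 and CRB3 (-2.3) in front (median -0.88, camera adjusted p = 5.3e-20). Of 21 other epithelial surface and protease genes 11 fell, 11 adjusted over the list alone (median -1.05, adjusted p = 5.4e-21). Epidermal differentiation genes fell in 8 of 26 cases, 8 adjusted over the list alone, among them the kallikreins KLK7 (-1.95) and KLK5 (-1.92) (adjusted p = 1.6e-13). Of 14 epithelial transcription and splicing regulators 3 fell, including OVOL2 (-1.84) and TFAP2C (-1.48) (adjusted p = 2.9e-05). Keratins KRT15 and KRT80 fell among 11 keratins (adjusted p = 0.0076), a list call lost with the other setting (adjusted p = 0.14 with an estimated correlation). Mesenchymal markers rose in 12 of 35 cases, 12 adjusted over the list alone (median 0.75, adjusted p = 5.3e-20), and with them 3 of 13 fibroblast markers (adjusted p = 6.2e-06). Of 21 collagens 4 rose, with COL6A1 at 1.64, and COL18A1 fell (-1.23, list adjusted p = 4.1e-05). Among the 25 matrix proteases and inhibitors 3 rose, LOX (2.4) and TIMP1 (1.52) most, and MMP9 fell (-1.22, list adjusted p = 0.0044). Glycolysis and hypoxia genes fell in 6 of 32 cases, 6 adjusted over the list alone, among them SLC2A1, the glucose transporter (-1.33) (adjusted p = 4.4e-09). Interferon response genes were higher as a list (adjusted p = 0.0089), but IFI6 (1.69) rose and IFIH1 (-1.12) fell.

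With the vector arrays as control, 215 of the 298 Snail calls were kept (72.1%). GDF15 (1.09 against parental, 0.99 without background correction) was then at -0.01 and FST (-1.83 against parental) at 0.25. Both changed sign, but neither was called. CLDN1, at -1.38 in vector against parental, was at -1.1 in Snail against vector. IL1B (-0.54), MMP9 (-0.01), KRT80 (-0.03), IFI6 (0.99) and HERC5 (0.84) no longer passed, and the list calls for keratins (adjusted p = 0.19) and interferon response (0.43) ended. With the mean of all probes KRT80 was at -0.77, and with the deposited values IFIH1 was at -1 and was not called.

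Slug-labelled arrays lost epithelial and epidermal genes and gained collagen genes. COL1A1 rose by 2.72 ± 0.09 (adjusted p = 3e-14), the clotting inhibitor TFPI by 2.37 ± 0.1, the proteoglycan BGN by 2.04 ± 0.1 and TAGLN by 2 ± 0.09. CST6, a cystatin of the skin barrier, fell from 10.22 ± 0.21 to 7.5 ± 0.19 (-2.72 ± 0.12, adjusted p = 1e-12). CLDN1 (-2.71 ± 0.11), KRT15 (-2.7 ± 0.11) and the membrane protease ST14 (-2.29 ± 0.1) fell alongside. CDH1 fell by 1.25 ± 0.1, and CDH2 (1.27 ± 0.13) and VIM (1.41 ± 0.09) rose, while FN1 stood at 0.79 ± 0.08, under the fold limit. These directions belong to arrays in which the SNAI2 probe read lower than in parental arrays. Whether that probe sees the introduced transcript is not known.

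In all, 173 genes were called between Slug and parental, 51 higher and 122 lower. Epithelial junction genes fell in 9 of 26 cases, 9 adjusted over the list alone (median -0.79, camera adjusted p = 9.4e-25), and other epithelial surface and protease genes in 9 of 21, 9 adjusted over the list alone (median -0.9, adjusted p = 4.7e-26). Epidermal differentiation genes fell in 10 of 26 cases, 10 adjusted over the list alone (median -0.68, adjusted p = 1.1e-19). Of 11 keratins 3 fell, 3 adjusted over the list alone, including KRT8 (-1.66) (median -0.6, adjusted p = 2.1e-08). TFAP2C (-1.19) and OVOL2 (-1.09) fell among the epithelial regulators (adjusted p = 3.5e-05). Of 35 mesenchymal markers 6 rose, 6 adjusted over the list alone (median 0.4, adjusted p = 1.6e-15), and 2 of 13 fibroblast markers rose with them (adjusted p = 1.3e-06). Collagens rose in 3 of 21 cases and COL18A1 fell (-1.54, list adjusted p = 0.00048). The matrix protease list did not pass (adjusted p = 0.49), with LOX (1.4) and TIMP1 (1.03) rising and MMP9 (-2.22) falling. Of 32 glycolysis and hypoxia genes 4 fell, 4 adjusted over the list alone, among them DDIT4 (-1.39) and BNIP3 (-1.16) (median -0.47, adjusted p = 1.8e-16). Interferon response genes were higher (adjusted p = 0.025), with IFI44 at 1.22, a list call lost otherwise (adjusted p = 0.075 with an estimated correlation).

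With the vector arrays as control, 138 of the 173 Slug calls were kept (79.8%), and 299 genes were called in all. FST, -1.05 against parental, was then called the other way at 1.03. CLDN1, -2.71 against parental, was at -1.33 against vector. PRKCA (0.84), TIMP1 (0.54), OVOL2 (-0.72), TFAP2C (-0.87) and COL5A2 (0.78) no longer passed, nor did the interferon list (adjusted p = 0.94). TIMP1 was at the fold limit: it was at 0.96 without parental replicate b and at 0.99 without Slug replicate c. FST was at -0.9 with the mean of its probes.

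**Figure D2:**
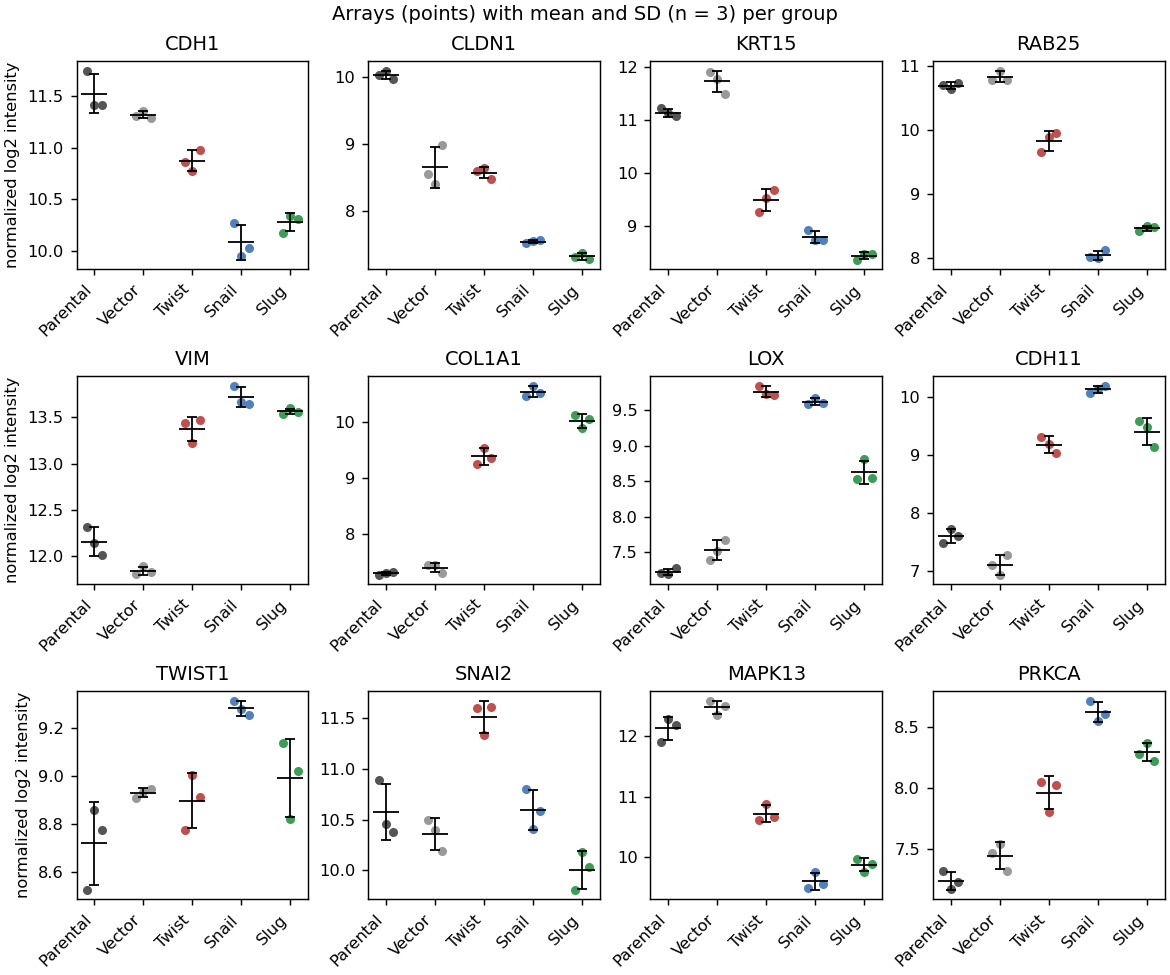
Normalized log2 intensity of 12 genes on each array (points) by group, with the group mean and SD (n = 3) as bars. For COL1A1, LOX, CDH11 and VIM all 9 factor arrays lie above the 6 parental and vector arrays, while SNAI2 is lowest in the arrays labelled Slug and CLDN1 is already lower in vector than in parental arrays.

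A shared set of genes moved the same way with all 3 factors. It held 51 genes, 20 higher and 31 lower. COL1A1, SPOCK1, LOX, SLCO2A1, CDH11, CDH2 and VIM were among those higher, with COL1A1 at 2.68 ± 0.07 in the mean of the factors. KRT15 (-2.23 ± 0.09), MAPK13 (-2.06 ± 0.09), PRSS8 (-1.86 ± 0.08) and CLDN7 (-1.78 ± 0.08) were among those lower, as were the hypoxia-responsive DDIT4 (-1.51 ± 0.07) and BNIP3, which fell in each group. Against both control groups 36 genes were shared, 16 higher and 20 lower, and CLDN1, CLDN7 and MMP9 were no longer among them. With vector alone as control 99 genes were shared, and with an offset of 16 in the background correction 85. The 3 comparisons use the same parental arrays, so that even the noise of unchanged groups correlates between them. Across genes, which are not independent replicates, r was 0.75 for Twist and Snail, 0.54 for Twist and Slug and 0.8 for Snail and Slug. Simulated unchanged groups gave 0.5, a value for noise without any change. The covariance was 0.069, 0.04 and 0.084 for these pairs, and 0.005 for each pair in the simulated groups. With 1 factor of the pair set against parental and the other against vector, so that no control array was shared, r was 0.62 and 0.5 for Twist and Snail, 0.36 and 0.41 for Twist and Slug and 0.56 and 0.71 for Snail and Slug. When 1 factor was set against parental and the others against vector, 56, 61 and 55 genes were shared, with the vector arrays still common to the others.

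For the mean of the 3 factors, 162 genes were called, 63 higher and 99 lower. Mesenchymal markers rose in 11 of 35 cases (camera adjusted p = 7.5e-23) and epithelial junction genes fell in 8 of 26 (adjusted p = 9.1e-21). Glycolysis and hypoxia genes fell in 5 of 32 cases (adjusted p = 1.6e-13) and fibroblast markers rose in 2 of 13 (adjusted p = 5e-08), with the same counts adjusted over the list alone in these 4 lists. Among fixed genes, FOSL1 was 0.53 ± 0.09 above parental and CD24 was at -0.45 ± 0.06, both under the fold limit. CD44 (0.26 ± 0.11, adjusted p = 0.09) and EGFR (-0.14 ± 0.08, adjusted p = 0.24) did not pass the adjusted p limit. Neither did PDGFRA (-0.11 ± 0.08, adjusted p = 0.36). The probes of CD44 differed: in Twist against parental its brightest was at 0.37 and the others at 0.82 and 0.08. CD24 was also lower in vector than in parental arrays (-0.37 ± 0.08, adjusted p = 0.002), and against vector the mean of the factors was at -0.08 for CD24, 0.84 for FOSL1 and 0.55 for CD44. ZEB1 and ZEB2 did not pass the filter on dim probes. In a fit without it, ZEB1 was at 0.22 ± 0.07 (adjusted p = 0.036) and ZEB2 at 0.35 ± 0.08 (adjusted p = 0.0045), both under the fold limit. With vector as control 101 of the 162 calls were kept (62.3%). CDH1 was then at -0.91, CLDN1 at -0.84 and PRKCA at 0.84, all under the fold limit, and FST (0.98) and KRT80 (0.25) changed sign.

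Further lists covered signalling pathways and cell states. In the mean of the 3 factors, the 27 TGF-beta and BMP pathway genes were higher (median 0.13, camera adjusted p = 0.01, then adjusted p = 0.033 with an estimated correlation). In Twist arrays BMP4 rose (1.25) and ID1 fell (-1.04), but BMP4 was at 0.86 and ID1 at -0.73 with the mean of their probes, and ID1 lost its call without parental replicate b (-0.94), without parental replicate c (-0.96) or without Twist replicate c (-0.98). EGF family ligands (7 genes, median -0.4, adjusted p = 0.0074), PDGF, FGF, HGF and VEGF ligands (16 genes, median -0.15, adjusted p = 0.033) and luminal markers (9 genes, median -0.1, adjusted p = 0.015) were lower, and p53 targets (17 genes, median 0.12, adjusted p = 0.037) higher. These 4 calls were lost with an estimated correlation, at adjusted p = 0.074, 0.088, 0.052 and 0.073, and with vector as control, at adjusted p = 0.14, 0.43, 0.76 and 0.96.

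Lists that did not pass in the mean of the factors were hemidesmosome and laminin-332 genes (adjusted p = 0.84), AP-1 factors (0.4), the Wnt pathway (0.4), mammary stem and progenitor markers (0.79), cell cycle (0.25), cytokines and chemokines (0.17), cholesterol synthesis (0.58) and the stress response (0.39). The marker lists of basal and myoepithelial (0.99), endothelial (0.67), leukocyte (0.36) and adipocyte (0.8) cells did not pass either. With vector as control, stem and progenitor markers (median 0.28, adjusted p = 0.028) and cholesterol synthesis (median 0.29, adjusted p = 0.0086) were higher. Both lists were lower in vector than in parental arrays, the stem and progenitor markers with a median of -0.25 (adjusted p = 0.0024, then adjusted p = 0.052 with an estimated correlation), and in the mean of the factors against parental their medians were 0.09 and 0.07. Single members moved in some of these lists: WNT5B rose (1.33 ± 0.08), as did HMOX1 (1.65 ± 0.12), and the chemokine CXCL16 fell (-1.5 ± 0.06). Between the factors, stress response genes were higher in Twist (median 0.22, adjusted p = 0.00016) and Snail (median 0.12, adjusted p = 0.00035) than in Slug-labelled arrays. Cell cycle genes (median -0.17, adjusted p = 0.00044) and EGF family ligands (median -0.3, adjusted p = 0.00044) were lower in Snail than in Slug-labelled arrays. These 4 calls passed with an estimated correlation too.

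**Figure D3:**
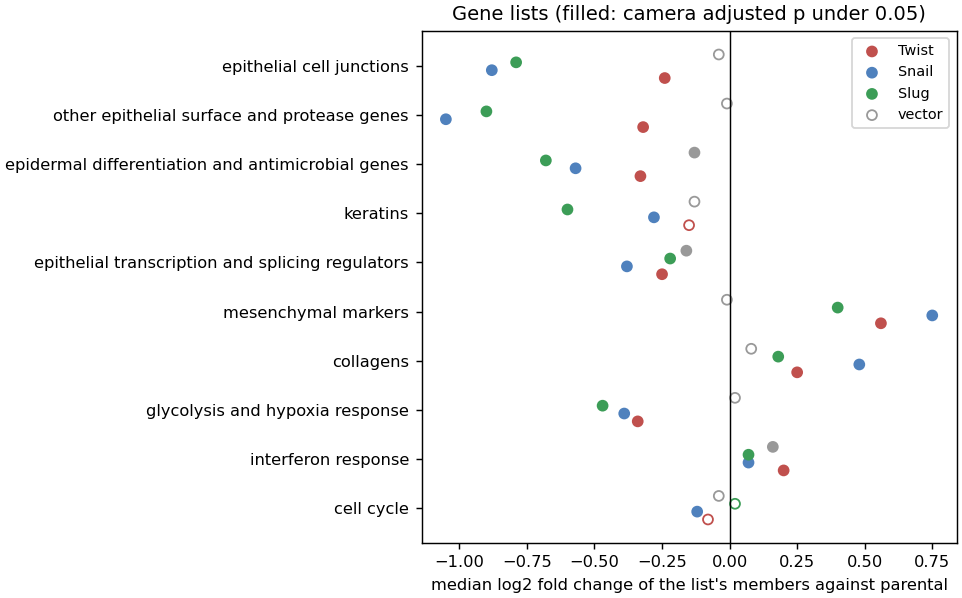
Median log2 fold change of the tested members of 10 gene lists in each factor and in vector arrays against parental arrays. Filled points have a camera adjusted p under 0.05 with the preset correlation. The epithelial junction medians are -0.24, -0.88 and -0.79 in Twist, Snail and Slug and -0.04 in vector arrays.

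Kinase genes changed in both directions between the parental arrays and the arrays of the 3 factors. In the mean of the 3 factors, SGK1, a kinase induced by growth factors and steroids (1.15 ± 0.07, adjusted p = 4.3e-11), and PRKCA, protein kinase C alpha (1.05 ± 0.07, adjusted p = 3.5e-10), rose. MAPK13, a p38 kinase, fell from 12.13 ± 0.19 in parental arrays (n = 3) to 10.07 ± 0.52 in factor arrays (n = 9), a change of -2.06 ± 0.09 (adjusted p = 1.8e-13). The receptor kinases FGFR3 (-1.78 ± 0.08), EPHA1 (-1.28 ± 0.07) and ERBB3 (-1.01 ± 0.08) fell too, ERBB3 only at the fold limit. MAPK13, FGFR3 and EPHA1 fell with each factor, and RPS6KA2 rose in Twist (1.54 ± 0.08). In the Snail arrays PRKCH (-1.29 ± 0.09), SYK (-1.2 ± 0.08) and LYN (-1.11 ± 0.07, and -0.84 against vector) fell.

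Of 356 kinases tested, 6 were called in the mean of the factors, 6 adjusted over the list alone (1.69%, against 1.33% of other genes, odds ratio 1.27, interval 0.456 to 2.86, Fisher's exact p = 0.48). Over the 8 comparisons the Fisher's exact p ran from 0.16 to 1 and the adjusted values from 0.96 to 1. As lists, the kinases (camera adjusted p = 0.23), the 38 receptor tyrosine kinases (0.44) and the 9 kinases of the protein kinase C and D family (0.35) did not pass in the mean of the factors. Against vector 7 kinases were called: SGK1 rose, and MAPK13, FGFR3, EPHA1, ERBB3, MKNK2 (-1.15) and MST1R (-1.19) fell. PRKCA passed the fold limit narrowly: without background correction it was at 0.97. In Twist against parental it was at 0.72 and was not called. Against vector it was at 0.51 in Twist and at 0.84 in the mean of the factors. ERBB3 was nearer still: it was at -0.89 without background correction, -0.87 with the deposited values, -0.94 with array weights and -0.68 with the mean of its probes, and it lost its call without parental replicate a (-0.92), without parental replicate b (-1), without Snail replicate a (-0.99) or without Slug replicate a (-0.98), and with array brightness as a covariate (-1). The kinase count was 5 with array weights and with brightness. It was 4, with a loss beyond ERBB3, in 3 other settings. Without background correction and with the deposited values 1 kinase was higher and 3 were lower. With the mean of all probes 2 were higher and 2 lower. EPHA1 in Twist was as narrow, at -0.98 without parental replicate a and at -0.96 without Twist replicate a. FGFR3 depends on its brighter probe, since another was at 0.04 and the mean of its probes at -0.87, and it was higher in vector than in parental arrays. With the mean of its probes no fall of FGFR3 in a single factor passed the fold limit (-0.94, -0.92 and -0.76 in Twist, Snail and Slug). Likewise, RPS6KA2 in Twist was at 0.83 with the mean of its probes.

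**Figure D4:**
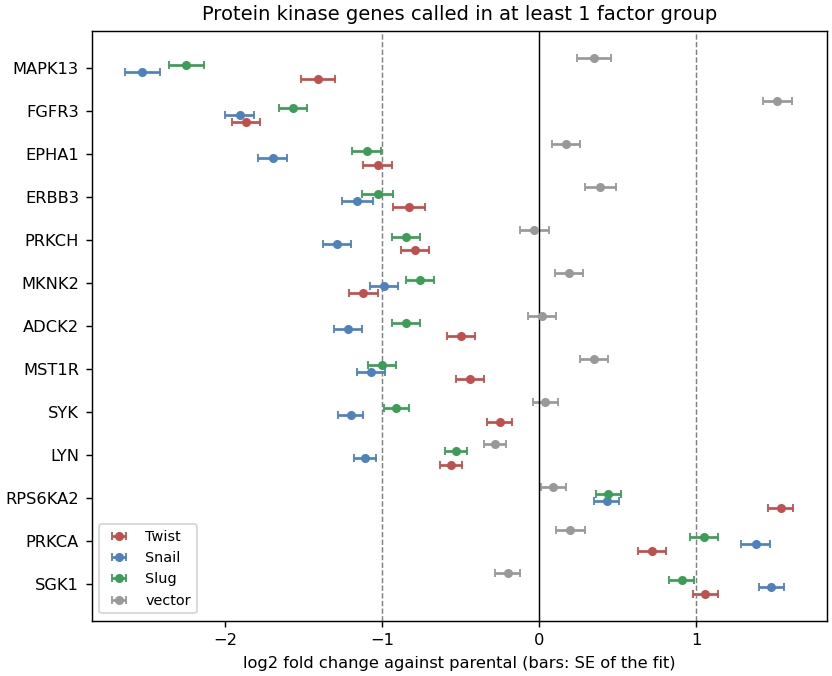
Log2 fold change against parental arrays of the 13 kinase genes called in at least 1 factor, with the standard error of the fit as bars (n = 3 arrays per group) and dashed lines at the fold limit. MAPK13 is at -1.41, -2.53 and -2.25 in Twist, Snail and Slug and at 0.35 in vector arrays, and FGFR3 is at 1.52 in vector arrays.

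Twist arrays had higher epithelial gene levels than Snail and Slug arrays. Against Snail, CST6 was 2.7 ± 0.12 higher (adjusted p = 4e-12), with IGFBP2 (2.37 ± 0.12), the tetraspanin TSPAN1 (2.24 ± 0.11) and PROM2 (1.93 ± 0.09) also higher. TAGLN (-1.79 ± 0.09), BGN (-1.66 ± 0.1) and JAM3 (-1.55 ± 0.1) were lower. Of 105 genes called, 82 were higher in Twist and 23 lower. Epithelial junction genes were higher in 5 of 26 cases, 5 adjusted over the list alone (camera adjusted p = 7.5e-22), other epithelial surface genes in 6 of 21 (adjusted p = 1.8e-26) and epidermal differentiation genes in 3 of 26 (adjusted p = 3.1e-14). Mesenchymal markers were lower as a list (median -0.23, adjusted p = 0.00059), although PRRX1 was higher (1.08, and 0.97 without background correction), and the difference in CDH1 (0.79 ± 0.1) stayed under the fold limit.

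Against Slug-labelled arrays, Twist arrays had more CST6 (3.8 ± 0.12, adjusted p = 1.9e-14), ASS1, the enzyme that makes argininosuccinate (2.34 ± 0.08), and COL8A1 (2.24 ± 0.09). JAM3 (-1.68 ± 0.1), BGN (-1.64 ± 0.1) and the retinal reductase DHRS3 (-1.69 ± 0.11) were lower. Among the called genes, 86 were higher in Twist and 20 lower. SNAI2 was 1.5 ± 0.13 higher in Twist than in Slug-labelled arrays (adjusted p = 4.7e-08). Junction genes were higher in 4 of 26 cases (camera adjusted p = 5.2e-14), other epithelial surface genes in 6 of 21 (adjusted p = 1.6e-17), epidermal differentiation genes in 5 of 26 (adjusted p = 7.4e-12) and keratins in 2 of 11 (adjusted p = 3.9e-06), with the same counts adjusted over the list alone. The mesenchymal list did not pass (adjusted p = 0.11).

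Snail and Slug arrays differed in few genes past the fold limit. By adjusted p alone 1603 genes differed, more than the 1349 between Twist and Snail. HMOX1 was 2.08 ± 0.15 higher in Snail (adjusted p = 8.8e-09) and the protease inhibitor TIMP2 1.51 ± 0.11 higher (0.95 with the mean of its probes), while DHRS3 (-1.8 ± 0.11) and IL1B (-1.33 ± 0.1) were lower. In all, 24 genes were called, 19 higher in Snail and 5 lower. With median scaling the share higher was 57.1% against 79.2% here. Mesenchymal markers (median 0.29, camera adjusted p = 1.8e-10), collagens (median 0.2, adjusted p = 0.0011) and matrix proteases and inhibitors (median 0.13, adjusted p = 3.6e-05) were higher in Snail. The junction list did not pass (adjusted p = 0.4). KRT8 (1.01 ± 0.1) passed only narrowly: it was at 0.87 with median scaling, at 0.89 without Slug replicate b and at 0.99 without Snail replicate c.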

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

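All tests of explanations in this part, those against other splits of the samples included, were chosen after the result had been seen.

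A few genes moved in opposite directions in groups compared with the same parental arrays, and the difference between them was fitted with limma. Except for SNAI2, the genes were picked for calls in opposite directions, so that a large difference with a small p follows from the choice and is no further evidence. ASS1 rose in Twist (1.23) and fell in Slug (-1.11), with a difference of 2.34 between them (adjusted p = 4.9e-14). CST6 rose in Twist (1.08) and fell in Slug (-2.72), with a difference of 3.8 (adjusted p = 1.9e-14), and fell in Snail too (-1.61). Against vector ASS1 in Twist was at 0.42, ASS1 in Slug was at -0.95 with the mean of its probes, and without parental replicate a CST6 in Twist was at 0.96, none of them called. SNAI2 differed by 1.5 (adjusted p = 4.7e-08), being higher in Twist and lower in Slug-labelled than in parental arrays. Other genes rose in vector arrays and fell in factor arrays. The mean of the 3 factors against vector was -3.3 for FGFR3 (adjusted p = 3.1e-17), -2.39 for KREMEN2 (adjusted p = 8.5e-16), -1.95 for NOTCH3 (adjusted p = 6e-15) and -2.16 for SPRR1A (adjusted p = 5.2e-10). NOTCH3 was 1.02 above parental in vector arrays, and -1.05 in Twist and -1.04 in Slug arrays. Without background correction these values were 0.94, -0.91 and -0.89, under the fold limit. Leaving out parental replicate a (0.98) or vector replicate a (0.97) ended the vector call, and leaving out parental replicate c ended those in Twist (-1) and Slug (-0.98). SPRR1A was 1.17 above parental in vector arrays with an SD of 0.55, and without vector replicate c it was at 0.92 and not called. FGFR3 and KREMEN2 in vector arrays were under the fold limit with the mean of their probes (0.76 and 0.83).

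Probes without a gene name also carried signal. Of 1581 such probes past the filter, 29 were called in at least 1 factor against parental, 7 of them the same way in all 3. Vector arrays, the other control, had 9 such calls against parental.

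The probes for the introduced factors showed no clear rise in the arrays named after them. An exchange of single arrays between groups is argued against, since 15 of 15 arrays correlated best with the other arrays of their own group. An exchange of the Twist and Slug groups as wholes cannot be told apart from correct labels, because the probes of the exchanged pair do not go together. SNAI2 was higher in Twist than in Slug-labelled arrays (1.5 ± 0.13, with 0.94 and -0.57 against parental), the direction that an exchange would give, while TWIST1 differed by -0.09, where an exchange seen by its probe would put it well below 0. Probes outside the introduced sequence may be the reason, as 0 of 3 factors rose by 1 or more in their own group, but the probe positions are not known and this stays open, as does lost expression of the introduced genes, which was not tested.

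Vector arrays differed from parental arrays in 33 genes past the fold limit. Array brightness as the whole cause is argued against, since 31 of the 33 calls stayed with brightness as a covariate. A response to transduction shared by all transduced cells may explain part of it. The change in the factor mean divided by that in vector had a median of 0.35 over the 33 genes (quartiles -0.04 and 0.82). Of these, 15 moved the same way by at least 0.5 times as much and 10 the opposite way. Both changes use the same parental arrays, which can by itself move them the same way, so this explanation stays open. Culture history and batch coincide with the groups and were not tested.

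Arrays of the same group deviated from one another along a leading component, which held 34.1% of the variance within groups. Array brightness is consistent with this pattern: r was 0.76 (exact permutation p = 0.0051 over 7776 rearrangements within groups) and rho 0.85 (exact permutation p = 0.0014). Without the 2 arrays farthest from the median brightness r was 0.74. What made the arrays differ in brightness stays open, and no biological explanation was tested.

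Other splits of the arrays bear on the counts of called genes. For comparisons of 3 arrays with 3, the real split alone, 1 of 10, gave as many genes, and 10 splits are too few for a share under 0.05. The real counts were 115 for Twist, 298 for Snail, 173 for Slug and 33 for vector against parental, 105 for Twist against Snail and 24 for Snail against Slug. In Twist against Slug, 86 genes were higher and 20 lower. The highest count of any other split was 0 in all 7 comparisons. For the mean of the 3 factors, in a fit of factor against parental arrays, the real count was 149 and the highest of the other splits 32, so that 1 of 100 gave as many. Among kinases the real count was 6 and the highest other 1, and for genes changed the same way by all 3 factors the values were 51 and 2, each with 1 of 100 splits as large. Splits that mix the groups also carry the differences between groups in their spread, which lowers their counts. These draws therefore cannot exclude a chance arrangement of single arrays for these 3 results. Chance between cultures is not excluded either, since the arrays of a group may share 1 culture.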

How the results depend on the processing

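Array brightness as a covariate, leaving out arrays for single genes and all alternatives for genes named outside the rule were chosen after the data had been seen; all other alternatives in this part were planned. Of the alternative counts of called genes, 223 stayed within 1.5 times the reported count and 20 did not. Calls by adjusted p alone numbered 1793 for Twist, 3222 for Snail, 2055 for Slug, 1764 for vector, 1349 for Twist against Snail, 2140 for Twist against Slug, 1603 for Snail against Slug, 2701 for the mean of the factors, 85 for kinases and 781 for genes shared by all 3 factors, larger by construction since the fold limit is dropped. With vector as control there were 185 for Twist, 299 for Slug and 99 shared, and the cause was not tested. An offset of 16, which by construction enlarges log changes of dim probes, gave 60 for vector, 162 for Twist against Snail, 164 for Twist against Slug, 42 for Snail against Slug and 85 shared. Vector had 21 without background correction and 20 with the deposited values. These calls were all among the 33 reported, and all 33 genes kept their sign in both settings. The cause was not tested.

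Among named genes, values on the same side of the limits numbered 7956, with 194 weaker, 13 stronger and 5 reversed. All 5 changed sign with vector as control: GDF15 (-0.01) and FST (0.25) in Snail, and FST in Slug (1.03). In the mean of the factors they were FST (0.98) and KRT80 (0.25). Only FST in Slug was called the other way. FST had fallen in vector arrays too (-2.08). The 7956 values include genes not called in their comparison. No filter, the median filter, the fit of compared groups, the robust prior and the replicate block gave 386 each and no other label. These settings do not alter the fold changes that decide the calls, so their values say nothing about stability. List tests kept their side in 552 cases, with 52 weaker and 16 stronger. Leaving out each array gave 108 to 121 genes for Twist, 291 to 323 for Snail, 169 to 187 for Slug, 31 to 39 for vector, 100 to 110 for Twist against Snail, 104 to 113 for Twist against Slug, 25 to 28 for Snail against Slug, 157 to 163 for the mean of the factors, 47 to 57 shared and 5 to 7 kinases.

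With median scaling the share higher was 33.3% against 54.5% in vector and 57.1% against 79.2% in Snail against Slug. Every gene past the fold limit had an adjusted p of at most 0.00023. The filters, the replicate block, the priors and a stricter adjusted p therefore leave these counts nearly fixed by construction and say nothing about stability. The same holds for list members counted with p-values adjusted over the list alone. A slide block was not run, because no slide is given. Signal over background limits dim genes: there are no detection p-values, and SNAI1, ZEB1 and ZEB2 fell to the filter on dim probes. Another probe of the gene moved the opposite way for 4 of 30 Twist, 4 of 69 Snail and 3 of 39 Slug calls with several probes, and another probe was under the fold limit for 25, 59 and 33 of them.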

Other observations

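The test in this part was chosen after the data had been seen.

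Genes that lie together on chromosome 1 may differ as a block between Twist and Slug-labelled arrays. This is a hypothesis. It was tested against genes scattered over the genome without order, with 12055 genes in chromosomal order, changes capped at 1 on the log2 scale, and the largest mean over 20 neighbouring genes compared with 1000 permutations of the gene order. In Twist against Slug the run from LCE5A to S100A4 had a mean of 0.43 (permutation p = 0.001, the smallest that these permutations can give, and adjusted p = 0.004 over 8 comparisons), with SPRR1B (1.85), S100A8 (1.55), S100A4 (1.3) and SPRR2D (1.26) called. An overlapping run was at 0.33 in Twist against Snail (permutation p = 0.001, adjusted p = 0.004) and at -0.32 in Slug against parental (permutation p = 0.009, adjusted p = 0.018). The run holds members of the epidermal differentiation list, so shared place and shared function cannot be separated here. In vector against parental, a run on chromosome 9 from INPP5E to DPP7 had a mean of 0.26 (permutation p = 0.007, adjusted p = 0.018). The other 4 comparisons did not pass, at adjusted values from 0.054 to 0.37.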
